A study of Homo sapiens with 6 samples.

How the data were processed

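RNA from ARPE-19 cells, an established human retinal pigment epithelium line, was sequenced after 72 h in normal or high glucose medium, with 3 libraries per group. Per the labels' protocols, total RNA was extracted with Trizol, passed over oligo-dT beads, fragmented and sequenced as read pairs on a NovaSeq instrument. The same protocol text also speaks of fractions with and without poly(A) and of adipose tissue, so how the RNA was selected is not settled by it. Structural RNAs without poly(A) tails (RN7SK, RN7SL1, RN7SL2, RPPH1 and RMRP) held 3.75% to 4.43% of the counts of each library. The labels give no glucose concentration, and they do not say whether the libraries of a group came from separate cultures.

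The authors deposited 1 table of 60835 loci with a count and an FPKM value per library. The deposited counts are whole numbers and were not normalized, per the file headers and values. The deposited FPKM values are scaled by the authors to locus length and library size, per the file headers, and they hold 0.0001 wherever the count is 0. The submitters' processing notes name Bowtie 0.12.2 and the mouse build mm8. The identifiers, gene names and coordinates in the table are human: of 32034 gene symbols that could be compared with the GRCh38.p14 annotation, 99.88% overlapped the position given there, so coordinates are printed as the table gives them. The counting tool is not given in the sources used here, and nothing states that strand was used, so reads of a gene and of an antisense partner may have been counted together.

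Of the loci, 33633 carry identifiers made by a transcript assembly step, and 3924 hold no annotated transcript. A locus was given a gene symbol only if it holds an annotated transcript. 2239 loci hold more than 1 name, and where a named gene shares its locus with another the text says so. Counts of 4, 8 and 12 were more frequent than their neighbours (9555 values of 4 against 4210 of 3 and 2659 of 5), so 1 fragment may have been counted about 4 times. The floor for a group without counts was therefore set at 3 fragments of 4 counts, or 12 counts per library, which is 0.137 to 0.147 CPM. Such floors cover counting error only. All 37 loci of the mitochondrial genome are listed at 0 and were left out as not measured. No per-sample column was left unmapped.

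Loci were filtered with filterByExpr, which kept 25025, and tested for high minus normal glucose with edgeR 4.0.16 (TMM scaling, glmQLFit and glmQLFTest, 2-sided, group as the only term) in R 4.3.3. Loci with a Benjamini-Hochberg adjusted p under 0.05 are referred to as called. CPM values are counts scaled to TMM library size (cpm in edgeR), log2 changes are edgeR estimates, and SE is the size of the estimate divided by the square root of its F statistic. 48 gene lists were fixed before the data were examined, as were the groups, the tests and the alternatives except those marked below. 47 of them had at least 5 measured members and were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry as alternatives. The 13 messenger RNAs of the mitochondrial genome form the list without a measurement. Pathway terms in the table's own annotation with 10 to 300 tested loci were tested for enrichment by a hypergeometric test, 1-sided, against the 5707 tested loci that carry a term.

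The design had assumed that the table would hold FPKM only, and stated edgeR for the case of counts, which applied. The alternatives that concern FPKM values (filters, pseudocounts of 1, 0.5 and 0.1, and limma with or without a trend) were run on the deposited FPKM. Other alternatives were DESeq2 1.42.0, other scalings, a replicate block, the omission of each library in turn and a minimum log2 change of 1. 3 alternatives were added after the data were seen: counts divided by 4, a voom fit with a weight per group, and list counts without the third normal glucose library. With 3 libraries per group that share only a number, no pairing was assumed.

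The genes named are the 10 called genes with the largest positive and the 10 with the largest negative log2 change among those whose groups did not overlap, leaving out loci without a name (clone accessions and RNA family names count as none). They are joined by up to 4 members with the smallest adjusted p of each list called by camera, up to 2 called members (or else the most abundant member) of the other lists described, and 18 genes fixed beforehand. Not every gene that met this rule is described. Genes named beyond this rule are marked as chosen after their values were seen.

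The edgeR and camera steps were tested on simulated data. This test was written and first run after the results on the real libraries had been seen, and nothing in the analysis was altered by it. It used counts drawn for the 25025 loci from the real means, library sizes and dispersions. Of 100 loci changed by a factor of 2, it called 15% in the right direction, and of 100 changed by a factor of 4 it called 51%. It called 4 of the 24825 unchanged loci. Each simulated locus had the same dispersion in both groups, while the real spread was 40.9% within normal and 27.1% within high glucose. The 4 calls are thus no rate of false calls for the real libraries. In a simulation with the members of 3 lists raised 2-fold, camera called all 3 lists, and 1 of the 38 lists that share no member with them. The simulated loci were drawn independently of each other. In the real data the estimated correlation was 0.845 in the unfolded protein response list and 0.802 in the G2 and M phase list. The 1 of 38 is thus no rate of false calls for the real lists. The library pairs within each group were compared by a chi-square statistic on counts divided by 4. It was 20.1 to 92.3 per degree of freedom, far above sampling noise, and each library was counted as its own sample.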

Results

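ARPE-19 cells, a human retinal pigment epithelium line, were compared after 72 h in high and in normal glucose medium, with 3 libraries per group. TXNIP and ARRDC4, arrestin family genes that rise when cells take up glucose, rose in high glucose. PHGDH and PSAT1, enzymes of serine synthesis, fell, as did SLC5A3 and SLC6A12, which import osmolytes. At an edgeR adjusted p under 0.05, 4906 of 25025 tested loci were called, 2439 higher and 2467 lower in high glucose, and 2617 of them (1333 higher, 1284 lower) differed by at least 2-fold. Of 13786 loci with a protein-coding transcript, 3517 (25.51%) were called, and the counts of called list members below are to be read against that share. The groups did not overlap at 42.31% of the loci. The share expected by chance is 10%, but loci vary together, and how far that share can stray was not assessed. The libraries held 81616741 to 87748820 counts and 30253 to 31698 loci with a count. The first principal component held 49.7% of the variance and placed normal glucose libraries 1, 2 and 3 at -88.4, -105.8 and -49.9 and the high glucose libraries at 79.2, 80.7 and 84.1, while the second (18%) set normal glucose 3 apart at -107.1. Variation between libraries, as the square root of the edgeR common dispersion, was 40.9% within normal and 27.1% within high glucose. The number of called loci changed when a library was left out. It was 2846, 2727 and 7615 without normal glucose 1, 2 and 3. It was 1631, 1421 and 1507 without high glucose 1, 2 and 3, a like drop for each. Only the omission of normal glucose 3 raised the number. The number of called members of the 47 gene lists changed too. It fell by more than 1.5 times in 21, 19 and 0 lists without normal glucose 1, 2 and 3. Without high glucose 1, 2 and 3 it fell by as much in 36, 42 and 39 lists. It grew by as much in 1 and 25 lists without normal glucose 2 and 3. An omission also leaves fewer libraries for the test. A lower number, or an adjusted p above 0.05, thus does not by itself show dependence on the library left out. The labels do not state that the libraries of a group are separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

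TXNIP, which restrains glucose uptake, rose from 1.09 ± 0.831 to 35.9 ± 3.34 CPM (n = 3; log2 change 5.04, SE 0.527; edgeR adjusted p = 0.00292), and by 5.88 without normal glucose 1. ARRDC4, a related glucose-responsive gene, rose from 10.6 ± 0.602 to 54.2 ± 3.52 CPM (n = 3; log2 change 2.35, SE 0.119; edgeR adjusted p = 4.58e-04). In the list of MondoA and ChREBP targets, 4 of 12 measured genes rose and 1 fell, and the same numbers were called when adjusted over the list alone, with a median log2 change of 0.32 (camera adjusted p = 0.195). The other 2 that rose were PFKFB3 (1.05) and KLF10 (1.77), and PFKFB4, whose locus also holds COL7A1 and UCN2, fell (-0.47); these 3 were chosen after their values were seen. PFKFB3 had an adjusted p of 0.0503 and 0.0542 without high glucose 2 and 3, and PFKFB4 of 0.0677 and 0.0568 without normal glucose 1 and 2 and of 0.0817, 0.107 and 0.0897 without high glucose 1, 2 and 3. Among 22 genes of glycolysis and glucose transport, 9 rose and 1 (PFKFB4) fell, or 12 and 1 when adjusted over the list alone, with a median of 0.63 (camera adjusted p = 0.0066; adjusted p = 0.705 with an estimated correlation). Of these, 5, 6 and 14 rose and 0, 0 and 3 fell without normal glucose 1, 2 and 3, and without high glucose 1, 2 and 3, 6, 4 and 4 rose and none fell. PFKL, a subunit of phosphofructokinase, rose from 131 ± 19.2 to 277 ± 11.1 CPM (log2 change 1.07, SE 0.129; edgeR adjusted p = 0.00406). TPI1, which interconverts triose phosphates, rose by 0.76 (SE 0.106; edgeR adjusted p = 0.00612). PGK1, an ATP-forming enzyme of glycolysis in a locus that also holds ATP7A, rose by 0.90, and PFKP, another phosphofructokinase subunit in a locus with PITRM1-AS1, by 0.68. SLC2A1, the main glucose transporter of these cells, was at 346 ± 112 and 380 ± 75.3 CPM (log2 change 0.13; edgeR adjusted p = 0.749).

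**Figure D1:**
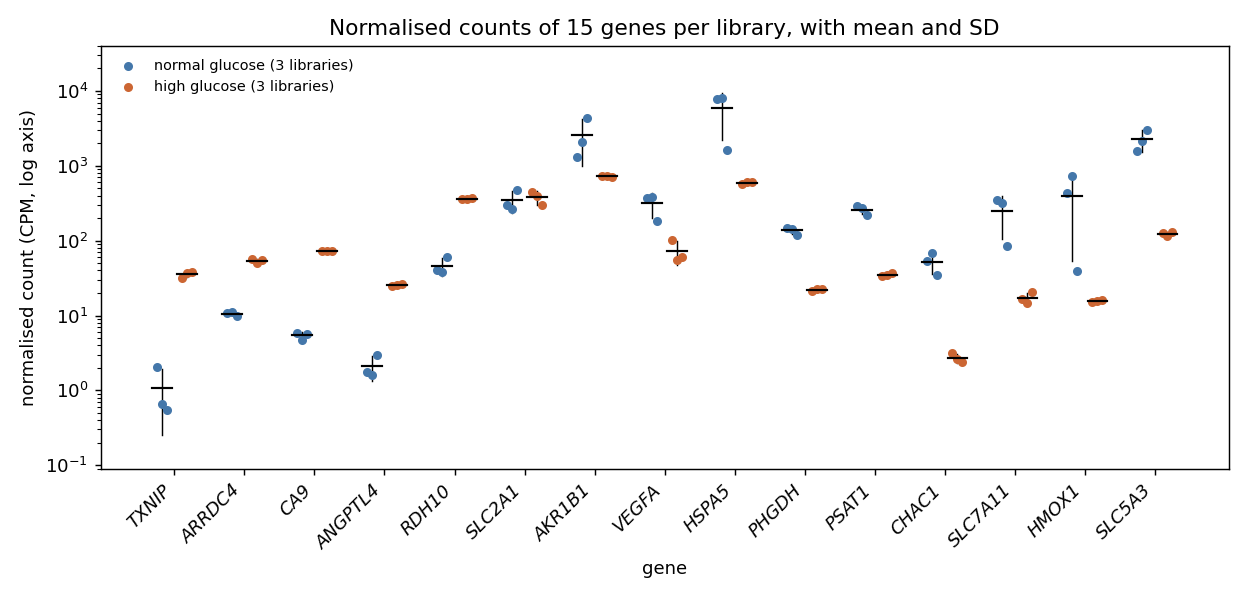
Normalised counts of 15 genes in each of the 6 libraries on a log axis. Bars give the mean and SD of the 3 libraries of a group.

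Most genes of the unfolded protein response list and of the ATF4 target list fell in high glucose. Of 26 unfolded protein response genes, 22 fell and none rose, or 26 when adjusted over the list alone, with a median log2 change of -1.69 (camera adjusted p = 3.88e-09; adjusted p = 0.705 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, fell from 5839 ± 3652 to 597 ± 22.1 CPM (n = 3; log2 change -3.29, SE 0.563; edgeR adjusted p = 0.0108), but its adjusted p was 0.0523, 0.0549 and 0.0546 without high glucose 1, 2 and 3. ATF4, the transcription factor of the integrated stress response, fell from 179 ± 21.7 to 84.6 ± 13.2 CPM (edgeR adjusted p = 0.0061). MANF, a secreted stress-induced protein, fell by 2.39 on the log2 scale, and TRIB3, a pseudokinase induced by stress, by 3.50. Of 26 ATF4 targets, 20 fell and none rose, or 22 when adjusted over the list alone, with a median of -1.91 (camera adjusted p = 9.45e-12; adjusted p = 0.705 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, fell from 137 ± 15 to 22.2 ± 0.776 CPM (log2 change -2.63, SE 0.122; edgeR adjusted p = 4.43e-04). PSAT1, the next enzyme of that path, fell from 261 ± 36.4 to 35.3 ± 1.76 CPM (log2 change -2.89, SE 0.138). SLC6A9, a glycine transporter, fell by 3.16, and CHAC1, which degrades glutathione, by 4.26. Unfolded protein response genes that fell numbered 10, 12 and 26, and ATF4 targets 17, 19 and 23, without normal glucose 1, 2 and 3, and without high glucose 1, 2 and 3, they numbered 4, 3 and 3, and 14, 14 and 15. The mean score of the unfolded protein response list was 1.27, 1.39 and -0.10 in normal glucose 1, 2 and 3 and -0.84, -0.86 and -0.85 in the high glucose libraries.

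Some genes of the osmotic and the NRF2 response fell, and others were not called or rose. Of 12 measured NFAT5 targets, which answer to hypertonic medium, 5 fell, SLC5A3, SLC6A12, NFAT5 and AKR1B1 among them, and 2 rose, HSPA4L among them, or 7 and 2 when adjusted over the list alone, with a median of -0.87 (camera adjusted p = 0.0329; adjusted p = 0.705 with an estimated correlation). The NFAT5 list was not called either with limma on log2 FPKM (camera adjusted p of 0.0857 to 0.088) or with a filter at FPKM 1 (0.103). Of the NFAT5 targets, 6, 5 and 6 fell and 2, 1 and 2 rose without normal glucose 1, 2 and 3, and without each high glucose library 2 fell and none rose. SLC5A3, the inositol transporter, in a locus with MRPS6, fell from 2252 ± 737 to 124 ± 7.15 CPM (n = 3; log2 change -4.18, SE 0.257; edgeR adjusted p = 0.001). SLC6A12, the betaine transporter, fell from 34 ± 26.5 to 0.589 ± 0.111 CPM (log2 change -5.85, SE 0.8; edgeR adjusted p = 0.00577), and by 5.15 without normal glucose 3. AKR1B1, the aldose reductase that makes sorbitol from glucose, fell by 1.85 (edgeR adjusted p = 0.022), by 1.24 without normal glucose 3, and with adjusted p of 0.0814, 0.0857 and 0.0855 without high glucose 1, 2 and 3. NFAT5 fell by 0.72 and was not called without high glucose 1, 2 or 3 (0.0622, 0.0619 and 0.0531), and HSPA4L, a chaperone, rose by 0.50 and was likewise not called (0.0626, 0.08 and 0.0814). In the list of polyol, hexosamine and pentose phosphate enzymes, 3 genes, AKR1B1 and KHK among them, fell and 1 rose, also when adjusted over the list alone, with a median of -0.17 (-0.29 to -0.09 over omitted libraries; camera adjusted p = 0.355). KHK, the fructose kinase, fell by 0.97 and had an adjusted p of 0.0663 without normal glucose 2 and of 0.091, 0.0973 and 0.0758 without high glucose 1, 2 and 3.

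Of 21 NRF2 targets, 8 fell and none rose, or 9 when adjusted over the list alone, with a median of -0.61 (camera adjusted p = 0.00613; adjusted p = 0.705 with an estimated correlation). NRF2 targets that fell numbered 6, 5 and 13, and those that rose 0, 0 and 2, without normal glucose 1, 2 and 3, and without high glucose 1, 2 and 3, 3, 2 and 3 fell. SLC7A11, the cystine importer, fell from 250 ± 145 to 17.2 ± 2.94 CPM (n = 3; log2 change -3.87, SE 0.525; edgeR adjusted p = 0.0057). HMOX1, which degrades heme, fell from 399 ± 345 to 15.5 ± 0.33 CPM (log2 change -4.69, SE 0.938; edgeR adjusted p = 0.0169), by 3.92 without normal glucose 2, and with adjusted p of 0.0729, 0.0754 and 0.0755 without high glucose 1, 2 and 3. GCLC, a glutathione synthesis enzyme, fell by 1.03 and had an adjusted p of 0.05 without high glucose 2. AKR1C3, a ketosteroid reductase, fell by 1.31, with adjusted p of 0.0647, 0.0668 and 0.0635 without high glucose 1, 2 and 3. Among 33 autophagy and lysosome genes, 8 fell and 1 rose, or 10 and 1 when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.00688; adjusted p = 0.705 with an estimated correlation). Of the lysosome list, 4, 4 and 18 fell without normal glucose 1, 2 and 3, and without each high glucose library 3 fell, with 1 that rose each time. TFEB, the transcription factor of lysosome genes, rose by 1.31 against this direction. NPC1, a cholesterol exporter of the lysosome, fell by 0.74, CTSK, a lysosomal protease, by 1.24, and MCOLN1, a lysosomal channel in a locus with PNPLA6, by 0.88.

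**Figure D2:**
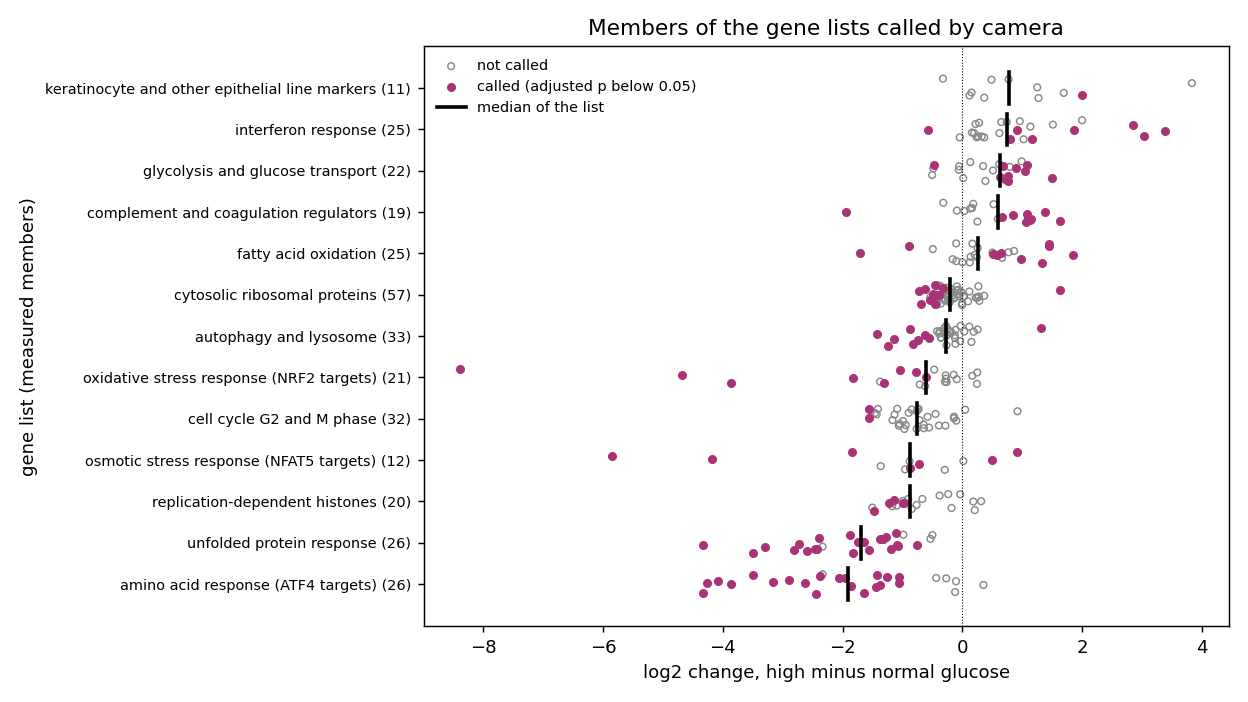
Log2 changes of the members of the 13 gene lists called by camera. Filled points are loci called by edgeR, and the leftmost NRF2 target, AKR1C2, had no count in high glucose.

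Most of the called interferon and complement genes rose in high glucose. Of 25 interferon response genes, 7 rose and 1 fell, or 12 and 1 when adjusted over the list alone, with a median of 0.74 (camera adjusted p = 3.41e-04; adjusted p = 0.705 with an estimated correlation). Interferon genes that rose numbered 4, 3 and 13, and those that fell 0, 0 and 1, without normal glucose 1, 2 and 3, and without high glucose 1, 2 and 3, 3, 3 and 4 rose. High glucose 1 stood apart on this list, with a mean score of 0.86 against 0.26 and 0.32 in high glucose 2 and 3. IFI44, an interferon-induced gene, rose from 0.846 ± 0.0818 to 6.93 ± 2.71 CPM (n = 3; log2 change 3.03, SE 0.319; edgeR adjusted p = 0.00293). SAMD9L, an antiviral factor, rose by 1.17. OASL, an antiviral protein, rose by 1.86 and had an adjusted p of 0.0582, 0.0502 and 0.054 without high glucose 1, 2 and 3, and OAS2, an RNA sensor, rose by 2.85 (2.07 without high glucose 1) and had one of 0.0517 and 0.0555 without normal glucose 1 and 2 and of 0.103 with voom and group weights. STAT2, a transcription factor of the response chosen after its value was seen, fell by 0.57, with adjusted p of 0.0562 and 0.057 without normal glucose 1 and 2 and of 0.104, 0.112 and 0.0922 without high glucose 1, 2 and 3. Of 19 complement and coagulation regulators, 9 rose and 1 fell, or 11 and 1 when adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.00511; adjusted p = 0.705 with an estimated correlation). Of the complement list, 8, 7 and 10 rose without normal glucose 1, 2 and 3, and without high glucose 1, 2 and 3, 6, 5 and 5. VTN, a component of drusen in a locus with SEBOX, rose by 1.37, and PLAUR, the urokinase receptor, by 1.14. CD55, which protects cells from complement, fell from 155 ± 40.1 to 40.5 ± 3.42 CPM. In the list of NF-kB and inflammatory genes, 3 genes, LIF and ICAM1 among them, rose and 1 fell, also when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.355). LIF, a cytokine that protects photoreceptors, rose from 94.2 ± 19.3 to 290 ± 6.28 CPM, and ICAM1, an adhesion receptor, from 145 ± 25.4 to 285 ± 3.19 CPM. IL6, an inflammatory cytokine, had a log2 change of -0.63 (edgeR adjusted p = 0.188) and was called without normal glucose 3 (-0.86; adjusted p = 0.0329), and CXCL8, a chemokine, of -0.13 (edgeR adjusted p = 0.837).

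Genes of hypoxia, matrix and epithelial identity changed in both directions. Of 25 angiogenesis and hypoxia genes, 5 rose, CA9, ANGPTL4 and THBS1 among them, and 6 fell, the same numbers when adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.601). CA9, a carbonic anhydrase of hypoxic cells, rose from 5.41 ± 0.579 to 72.9 ± 1.02 CPM (n = 3; log2 change 3.75, SE 0.132; edgeR adjusted p = 1.55e-04), and ANGPTL4, a lipase inhibitor, from 2.11 ± 0.76 to 25.5 ± 0.593 CPM. VEGFA, the main factor for vessel growth, fell from 315 ± 114 to 73.2 ± 26 CPM (log2 change -2.10, SE 0.352; edgeR adjusted p = 0.01), with adjusted p of 0.0505 and 0.0531 without high glucose 2 and 3. Of 25 genes of TGF-beta signalling, 9 rose and 5 fell, also when adjusted over the list alone, with a median of 0.32 (camera adjusted p = 0.184). SMAD3, its signal carrier, rose by 1.06 and INHBA, an activin subunit, by 2.04. Of 19 genes of epithelial-mesenchymal transition, 6 rose and 2 (ZEB2 and TWIST1) fell, or 6 and 3 when adjusted over the list alone, and the median of 0.04 and mean of -0.01 differed in sign (camera adjusted p = 0.568). ZEB2, a repressor of epithelial genes, fell by 0.76, and PDGFRB, a growth factor receptor, rose by 0.68. TWIST1, a repressor in the same program, fell by 0.89 and had an adjusted p of 0.0594 and 0.0526 without normal glucose 1 and 2 and of 0.084, 0.0627 and 0.0879 without high glucose 1, 2 and 3. FN1, a matrix glycoprotein, and CDH2, a cadherin, had log2 changes of 0.24 and -0.12 (edgeR adjusted p = 0.166 and 0.561). Among 28 fibrillar collagen and matrix genes, 4 rose and 2 fell, or 5 and 2 when adjusted over the list alone, and the median of -0.28 had the opposite sign to the camera test, which pointed up (camera adjusted p = 0.733). Normal glucose 1 stood apart on this list, with a mean score of 0.996 against -0.38 and -0.53 in normal glucose 2 and 3, and without it the median was 0.26. It also did on 11 measured fibroblast markers (1.14 against -0.37 and -0.08), of which PDGFRB rose and 2, TWIST1 among them, fell, or 1 and 3 when adjusted over the list alone, with a median of -0.55 (camera adjusted p = 0.525), and of 0.03 without normal glucose 1. FBN1, a microfibril protein, rose by 1.07, and THBS1, a matrix glycoprotein that blocks vessel growth, by 0.91, with an adjusted p of 0.0502 for THBS1 without high glucose 2. Of 22 basement membrane genes, 5 rose and 2 fell, or 6 and 2 when adjusted over the list alone (camera adjusted p = 0.317), and COL4A1, a network collagen, rose from 101 ± 13.1 to 274 ± 6.84 CPM and LAMB3, a laminin chain, by 1.10.

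Of 21 metalloproteases and inhibitors, 6 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.61). MMP24, a membrane protease, rose by 2.55, and TIMP3, a protease inhibitor mutated in a macular dystrophy, fell by 0.78. Of 25 measured genes of retinal pigment epithelium identity, 4 rose and 2 fell, or 6 and 3 when adjusted over the list alone, with a median of 0.12 (0.04 to 0.30 over omitted libraries; camera adjusted p = 0.568). RDH10, a retinol dehydrogenase, rose from 46.6 ± 12.5 to 366 ± 9.3 CPM (n = 3; log2 change 2.97, SE 0.197; edgeR adjusted p = 0.00125), and KRT18, a keratin of simple epithelia, from 245 ± 99.3 to 898 ± 46 CPM. BEST1, a chloride channel of this epithelium chosen after its value was seen, fell by 2.21, with adjusted p of 0.0551 and 0.0545 without high glucose 1 and 2. RLBP1, a retinoid carrier, was at 2.33 and 1.84 CPM (edgeR adjusted p = 0.707), and RPE65, the retinoid isomerase, had counts of 0, 3 and 0 in normal and 0, 4 and 0 in high glucose and was not tested. Of 24 junction genes, 7 rose and 2 fell, or 8 and 3 when adjusted over the list alone, and the median of -0.01 and the mean of 0.20 differed in sign (camera adjusted p = 0.436). CLDN4, a claudin, rose by 1.60. NECTIN2, an adhesion protein, rose by 0.53 and had an adjusted p of 0.0539, 0.0588 and 0.0531 without high glucose 1, 2 and 3. TJP1, a scaffold of tight junctions, had a log2 change of -0.27 (edgeR adjusted p = 0.281) and was called without normal glucose 3 (-0.43; adjusted p = 0.0139). Of 11 keratinocyte and other epithelial markers, KRT7 alone rose, also when adjusted over the list alone, with a median of 0.77 (camera adjusted p = 0.0468; adjusted p = 0.705 with an estimated correlation). The camera adjusted p was 0.323, 0.0672 and 0.0772 without normal glucose 1, high glucose 1 and high glucose 2, and the median was 0.46 without normal glucose 1 and 1.45, with 2 members that rose, without normal glucose 3. The list score was -2.16, -0.46 and 0.32 in normal glucose 1, 2 and 3. KRT7, a keratin of simple epithelia, rose from 221 ± 92.5 to 886 ± 53.2 CPM. KRT16, ESRP1 and SFN, epithelial genes, had edgeR adjusted p of 0.0678, 0.0885 and 0.333, and KRT16 was called without normal glucose 3 (7.41; adjusted p = 0.0176). The endothelial markers KDR and ROBO4, receptors of vessel cells, fell by 2.41 and 1.06 on the log2 scale.

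Most of the called genes that burn fatty acids rose. Of 25 fatty acid oxidation genes, 8 rose and 2 fell, or 10 and 2 when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0329; adjusted p = 0.705 with an estimated correlation). The list was not called either with limma on log2 FPKM (camera adjusted p of 0.0575 to 0.0719) or with a filter at FPKM 1 (0.0743). Its camera adjusted p was 0.0746 without normal glucose 1, its median was 0.43 without normal glucose 2, and 10 rose and 3 fell without normal glucose 3. The number that rose was 4 and 6 without normal glucose 1 and 2, and without each high glucose library 4 rose, with 2 that fell each time. EHHADH, an enzyme of peroxisomal oxidation, rose by 1.44, and CPT2, which readies fatty acids inside mitochondria, by 1.45. CPT1B, which admits fatty acids to mitochondria, in a locus with CHKB, fell by 0.88, and PPARGC1A, a regulator of mitochondrial genes, by 1.71. Of 41 nuclear-encoded genes of oxidative phosphorylation, 5 rose and 1 fell, also when adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.0787). The median was 0.11 without normal glucose 2 and 0.34 without normal glucose 3 (camera adjusted p = 0.00198; 15 rose and 2 fell). Of these genes, 0 and 1 rose without normal glucose 1 and 2, and without each high glucose library none was called. PLIN2, a lipid droplet protein in a locus with HAUS6, rose by 1.30. PCK2, a mitochondrial enzyme of glucose synthesis, fell by 2.13.

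The called genes of mitosis and histones fell, with normal glucose 3 standing apart on both lists. Most called ribosomal protein genes fell as well, and there the list score was 0.02, 0.13 and 0.10 in normal glucose 1, 2 and 3. Of 32 genes of G2 and M phase, BIRC5 and CDC25C fell, also when adjusted over the list alone, with a median of -0.76 (camera adjusted p = 0.0175; adjusted p = 0.814 with an estimated correlation). The list score was 0.15, -0.52 and 1.2 in normal glucose 1, 2 and 3, and the median was -0.11 without normal glucose 3 (camera adjusted p = 0.626; 1 rose and 3 fell), -1.16 without normal glucose 2 and -0.81 without high glucose 1 (camera adjusted p = 0.0574). Mitotic genes that fell numbered 1 and 8 without normal glucose 1 and 2, and without high glucose 1, 2 and 3, 1, 0 and 0. BIRC5, survivin, fell by 1.55, with adjusted p of 0.0598 and 0.0583 without high glucose 2 and 3. CDC25C, a phosphatase that starts mitosis, fell by 1.56, with adjusted p of 0.0521 without normal glucose 1 and 0.0742, 0.0577 and 0.074 without high glucose 1, 2 and 3. PTTG1, securin, and PLK1, a mitotic kinase, had edgeR adjusted p of 0.0616 and 0.0774; PTTG1 was called without normal glucose 2 (0.038) and 3 (0.0473), and PLK1 without normal glucose 2 (0.0263). Of 20 replication-dependent histone genes, 5 fell, H4C2, H1-4, H2BC5 and H2AC6 among them, also when adjusted over the list alone, with a median of -0.88 (camera adjusted p = 0.0329; adjusted p = 0.814 with an estimated correlation). The histone median was -0.16 without normal glucose 3 (camera adjusted p = 0.365; 2 rose and 6 fell) and -0.78 without high glucose 1 (camera adjusted p = 0.0754), and without high glucose 1, 2 and 3, 1, 1 and 2 fell. H4C2, which packs DNA, fell by 1.23. The linker histone H1-4 had an adjusted p of 0.05 and 0.0534 without high glucose 1 and 2, H2BC5 of 0.0869, 0.0844 and 0.079 without high glucose 1, 2 and 3, and H2AC6 of 0.0909 without normal glucose 2 and 0.082, 0.115 and 0.0974 without high glucose 1, 2 and 3. Of 57 cytosolic ribosomal proteins, 11 fell and 1 rose, or 13 and 1 when adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.00563; adjusted p = 0.705 with an estimated correlation). Ribosomal protein genes that fell numbered 7, 4 and 19, and those that rose 0, 0 and 3, without normal glucose 1, 2 and 3, and without high glucose 1, 2 and 3, 2, 2 and 1 fell and 0, 1 and 0 rose. RPL13A, a large subunit protein in a locus with ALDH16A1 and FLT3LG, fell by 0.69. RPS9 and RPL3, proteins of the small and large subunit, fell by 0.62 and 0.46, with adjusted p of 0.051, 0.0546 and 0.0572 for RPS9 and 0.0726, 0.077 and 0.0751 for RPL3 without high glucose 1, 2 and 3. RPL29, a large subunit protein with near-identical copies in the genome, rose by 1.64, with adjusted p of 0.0601, 0.0622, 0.0676 and 0.0712 without normal glucose 1, normal glucose 2, high glucose 1 and high glucose 3 and of 0.0636 with voom and group weights. CDKN1A, an inhibitor of the cell cycle, was at 277 ± 215 and 314 ± 268 CPM (edgeR adjusted p = 0.884).

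Among loci with a gene name whose groups did not overlap, the 10 largest fitted log2 rises and 9 of the 10 largest falls were at genes without a count in 1 group, where only a lower bound of the fold is known, so this ranking is not one by fold: CA9, counted in both groups, rose by 3.75 on the log2 scale. ARL14, a vesicle GTPase, was at least 5.14-fold higher, RNF212, a meiotic protein, at least 3.97-fold, CD200R1, an immune receptor, at least 3.77-fold, the non-coding LINC02028 at least 3.34-fold and ADAM28, a protease, at least 2.88-fold. The pseudogene MBL1P was at least 2.5-fold higher, CYP4A22, a fatty acid hydroxylase, at least 2.34-fold, the pseudogene RDM1P5 at least 2.25-fold, the non-coding LINC02696 at least 2.08-fold and GSTA1, a glutathione transferase, at least 2.03-fold. VIP, a neuropeptide, had no count in high glucose and was at least 11.5-fold lower, CALCB, a calcitonin gene-related peptide, at least 3.8-fold, AKR1C2, a ketosteroid reductase, at least 3.5-fold and the non-coding LINC00491 at least 3.09-fold. ANKRD34C, MMP23B, ST13P21, OOSP1 and PRPH, a neuronal filament gene, were at least 2.85, 2.73, 2.56, 2.55 and 2.16-fold lower. IL1RL1, an interleukin receptor in a locus with IL18R1, fell to 0.0603 CPM. With voom and group weights the adjusted p was 0.215 for IL1RL1 and 0.0532 for MBL1P. Without normal glucose 2 the log2 change was -7.84 for CALCB, -6.97 for OOSP1 and -7.16 for IL1RL1, against -8.51, -7.93 and -7.75, and without normal glucose 3 that of AKR1C2 was -7.79, against -8.38. Without high glucose 1, the edgeR adjusted p was 0.0563 for ADAM28, 0.0781 for MBL1P, 0.0593 for CYP4A22, 0.0662 for RDM1P5, 0.061 for LINC02696, 0.0793 for GSTA1, 0.0563 for CALCB, 0.0521 for ANKRD34C, 0.0672 for OOSP1, 0.0561 for IL1RL1 and 0.0547 for PRPH. Without high glucose 2 it was 0.0553 for CD200R1, 0.0545 for ADAM28, 0.0732 for MBL1P, 0.0561 for CYP4A22, 0.0697 for RDM1P5, 0.0695 for LINC02696, 0.0561 for GSTA1, 0.0599 for CALCB, 0.055 for ANKRD34C, 0.0695 for OOSP1, 0.0595 for IL1RL1 and 0.0568 for PRPH. Without high glucose 3 it was 0.0663 for CYP4A22, 0.0531 for RDM1P5, 0.0807 for LINC02696, 0.0797 for GSTA1, 0.0581 for CALCB, 0.0538 for ANKRD34C, 0.0677 for OOSP1, 0.0546 for IL1RL1 and 0.0552 for PRPH. Without normal glucose 1 it was 0.0623 for CALCB, 0.0651 for OOSP1 and 0.0549 for PRPH. Without normal glucose 2 it was 0.0632 for CALCB, 0.0503 for AKR1C2, 0.053 for LINC00491, 0.0634 for ANKRD34C, 0.0506 for MMP23B, 0.0527 for ST13P21, 0.0765 for OOSP1 and 0.0665 for PRPH.

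Non-coding loci changed as well, and the longest run of loci called in 1 direction lies on chromosome 6. The composition of the libraries also moved with the groups: loci with ribosomal RNA held 1.47% to 1.74% of the counts in normal and 1.11% to 1.24% in high glucose, long non-coding loci 1.96% to 2.06% and 1.64% to 1.79%, and protein-coding loci 88.8% to 89.7% and 90.1% to 90.8%. Of 4381 loci with long non-coding transcripts only, 261 rose and 202 fell, and of 3442 assembled loci without an annotated transcript, 241 rose and 396 fell. The number of called long non-coding loci was 463, and 259, 226 and 738 without normal glucose 1, 2 and 3 and 130, 108 and 106 without high glucose 1, 2 and 3. Of 31 well-known long non-coding RNAs, 5 rose, TUG1 among them, and 6 fell, or 5 and 9 when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.436). TUG1, a chromatin regulator, rose by 0.54, with edgeR adjusted p of 0.0611, 0.0676 and 0.0572 without high glucose 1, 2 and 3. DANCR, a regulator of differentiation in a locus that also holds LINC01618 and RASL11B, fell by 1.99. MALAT1 and NEAT1, nuclear RNAs, had log2 changes of 0.20 and -0.38 (edgeR adjusted p = 0.832 and 0.738), and MEG3, an imprinted RNA, of -1.07 (edgeR adjusted p = 0.459). On chromosome 6, 27 adjacent tested loci from 74069451 to 74734279, 23 of them without an annotated transcript, all fell, with a median log2 change of -4.61 and a range of -8.38 to -3.35. Their summed level was 499, 440 and 128 CPM in normal glucose 1, 2 and 3 and 15.5, 13 and 13.5 CPM in the high glucose libraries. The longest run over 1000 shuffled orders held 7 loci. Shuffling treats adjacent loci as independent, which pieces of 1 transcript are not. Runs of at least 5 loci numbered 17. Runs of 9 loci on chromosome 9 (median log2 change 6.52) and of 8 loci on chromosomes 21 (-3.73) and 8 (-1.45) also exceeded 7. The run on chromosome 21 begins with the locus of SLC5A3. The nearest protein-coding genes on either side of the chromosome 6 run were CD109, a surface protein, and COL12A1, a collagen. They had log2 changes of 0.43 and -0.35 and were not called. Of 16 protein-coding loci within 1.5 Mb, 2 were called: CGAS, a sensor of cytosolic DNA, fell by 1.67 (edgeR adjusted p = 0.00926) and EEF1A1, a translation factor, by 0.77 (edgeR adjusted p = 0.00459). These runs, and the flanking genes of the chromosome 6 run, were chosen after their values were seen.

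**Figure D3:**
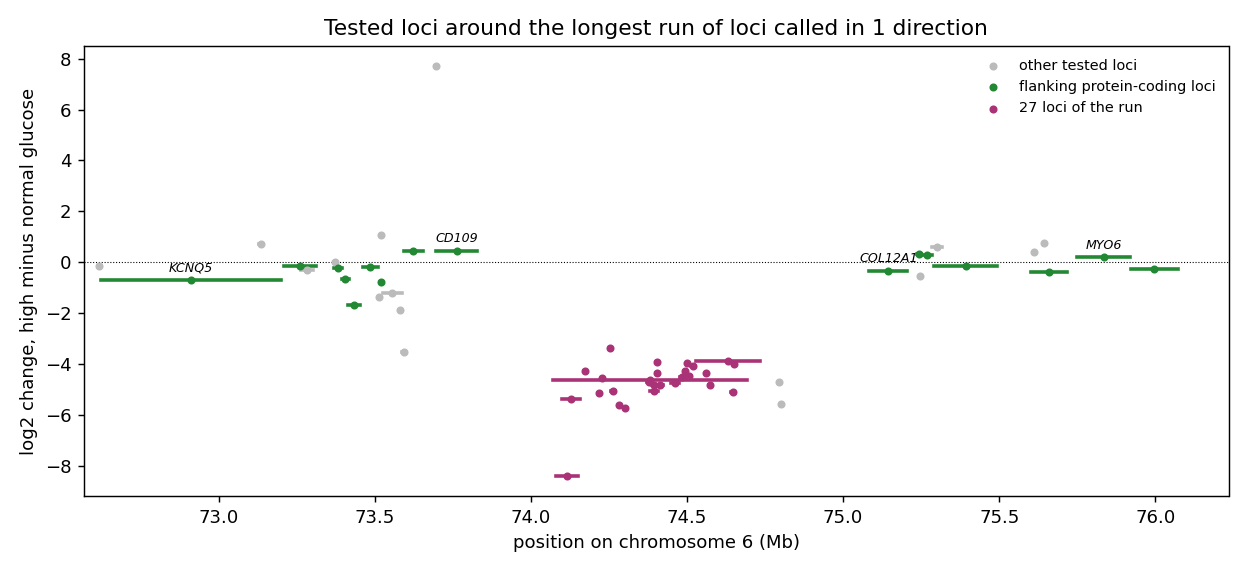
Log2 changes of tested loci along chromosome 6 around the run. Named points are flanking genes.

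In the pathway annotation of the deposited table, protein processing in endoplasmic reticulum was enriched among lower loci (48 of 156; hypergeometric adjusted p = 1.23e-06), as was thyroid hormone synthesis (17 of 53; hypergeometric adjusted p = 0.0405). Proteasome (15 of 42) and complement and coagulation cascades (16 of 47) were enriched among higher loci (hypergeometric adjusted p = 0.0408 for both). The hypergeometric test treats the loci of a term as independent of each other, and it was not repeated without each library. No gene list was called by camera when the correlation between members was estimated from the data, where the lowest adjusted p was 0.705 and 2 of 47 lists had an unadjusted p under 0.05. Camera with its preset correlation also called 13, 12 and 13 lists for the 3 splits that put normal glucose 1 and 2 together with 1 high glucose library, as against 13 for the real groups. These splits still set normal glucose 1 and 2 against the other high glucose libraries, so they are no measure of chance.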

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

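The direction of the main results held across settings, but the number of calls did not. Against 4906 called loci (2439 higher, 2467 lower), 463 called long non-coding loci and 13 called lists, leaving out each library in turn gave 1421 to 7615 called loci (730 to 3932 higher, 691 to 3683 lower), 106 to 738 long non-coding loci and 10 to 14 lists. A minimum log2 change of 1 left 2617 (1333 higher, 1284 lower). A filter at FPKM 5 gave 2335 (1172 higher, 1163 lower), 24 long non-coding loci and 7 lists, and one at FPKM 1 gave 189 long non-coding loci and 7 lists; a filter on abundance removes loci before the test. A replicate block gave 2545 (1312 higher, 1233 lower) and 206 long non-coding loci, and deviations of libraries with the same number did not pair (r = -0.017, -0.001 and -0.009). Limma on log2 FPKM gave 222, 216 and 207 long non-coding loci at pseudocounts of 1, 0.5 and 0.1, 229 without a trend and 216 with robust fitting, and DESeq2 gave 768. With an estimated correlation 0 lists were called, and 2 had an unadjusted p under 0.05. Counts divided by 4 (5326 called) and voom with group weights (5146), both chosen after the data were seen, moved no count by as much. Of 131 called named genes none changed sign where tested, but only 105 were tested with limma on log2 FPKM and 78 at FPKM 5. The block kept 97 of the 131 called, and 89, 83 and 90 stayed called without high glucose 1, 2 and 3. List calls also moved: the osmotic list was lost with limma on FPKM (camera adjusted p of 0.0857 to 0.088) and at FPKM 1 (0.103), and the fatty acid oxidation list likewise (0.0575 to 0.0719, and 0.0743). At FPKM 1 and FPKM 5 the NRF2 (0.0501 and 0.251), G2 and M phase (0.0606 and 0.421) and histone lists (0.0616 and 0.149) were lost, and at FPKM 5 the interferon list (0.258). The keratinocyte list was lost with scaling to totals (0.0582), at FPKM 0.1 (0.0655) and with counts divided by 4 (0.152). Gains were oxidative phosphorylation with scaling to totals (0.0437), quantile scaling (0.0242) and limma on log2(FPKM + 1) (0.0458), and endothelial markers with scaling to totals (0.0437), quantile scaling (0.0494) and the block (0.0494). Fry, which tests a list without reference to other genes, called 16 lists: it missed 4 that camera called, the unfolded protein response (fry adjusted p = 0.0576), G2 and M phase (0.453), histone (0.343) and keratinocyte (0.0844) lists, and added MondoA (0.004), polyol (0.0109), TGF-beta (0.0303), junction (0.0258), ferroptosis (0.038), structural RNA (0.038) and endothelial (0.0309) lists. Signs changed only at genes and list medians that were not called, among them the fibrillar collagen (-0.336 to 0.257 over omitted libraries), cholesterol synthesis (-0.128 to 0.383), NF-kB (-0.09 to 0.423), epithelial-mesenchymal transition (-0.105 to 0.215) and antioxidant (-0.057 to 0.314) medians. CXCL8 was 0.059 with quantile scaling, 0.046, 0.048 and 0.05 with limma at the 3 pseudocounts, 0.046 without a trend or with robust fitting, 0.014 with the block, 0.006 with voom and -0.426 to 0.423 over omitted libraries. MALAT1 was -0.016, -0.017 and -0.017 with limma, -0.016 without a trend or with robust fitting, -0.05 with the block, -0.053 with voom and -0.109 to 0.645 over omitted libraries. NEAT1 was 0.177 with quantile scaling, 0.056, 0.107 and 0.169 with limma, 0.056 without a trend or with robust fitting, 0.063 with the block, 0.15 with voom and -0.875 to 0.464 over omitted libraries. Over omitted libraries SLC2A1 was -0.031 to 0.428, RLBP1 -0.72 to 0.563, CDKN1A -0.795 to 1.038, MEG3 -1.521 to 0.788 and the S phase median -0.544 to 0.399. The cause was not tested.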

Other observations

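Among the lists not called by camera, single genes still changed. Of all tested protein-coding loci 25.51% were called, so a count near or below that share is no result about the list. Of 25 genes of p53 targets, 5 rose and 4 fell, or 5 and 7 when adjusted over the list alone (camera adjusted p = 0.61): FAS, a death receptor, rose by 1.37 and CCNG1, a cyclin, fell by 1.16. Of 28 apoptosis genes, 4 rose and 5 fell, or 7 and 5 when adjusted over the list alone (camera adjusted p = 0.682): BCL2, which blocks apoptosis, fell by 1.94, and PMAIP1, which promotes it, by 0.81, with an edgeR adjusted p of 0.0519 without high glucose 2. Of 22 ferroptosis genes, 1 rose and 7 fell, or 1 and 8 when adjusted over the list alone, and the median of 0.03 and mean of -0.70 differed in sign (camera adjusted p = 0.43): CHAC1, SLC7A11 and HMOX1, all named above, were among those that fell. Of 19 heat shock genes, 4 rose and 2 fell, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.436): DNAJB4, a co-chaperone in a locus with GIPC2, rose by 1.95 and HSPB1, a small chaperone, by 0.93. Of 24 antioxidant enzymes, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.754): PRDX6, a peroxiredoxin, rose by 0.81. Of 25 immediate early genes, 4 rose and 4 fell, or 4 and 5 when adjusted over the list alone (camera adjusted p = 0.985): KLF4 and IER3, early transcription and survival factors, fell by 2.09 and 1.59 on the log2 scale. Of 20 Hippo targets, 8 rose and 1 fell, or 8 and 2 when adjusted over the list alone (camera adjusted p = 0.106, and 0.0421 without normal glucose 1): F3, tissue factor, rose by 1.10 and AJUBA, a scaffold in a locus with HAUS4, fell by 1.45. Of 23 Wnt and Notch targets, 2 rose and 4 fell, or 3 and 4 when adjusted over the list alone (camera adjusted p = 0.568): DKK1, a Wnt inhibitor, fell by 1.55 and HES1, a Notch target, rose by 2.24. Of 21 insulin axis genes, 2 rose and 3 fell, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.754): IRS1, an insulin receptor substrate, fell by 0.74 and IGFBP3, a growth factor carrier, rose by 1.28.

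Some genes of lipid, energy and replication lists were called too. Of 24 cholesterol synthesis genes, 3 fell, also when adjusted over the list alone, and the median of 0.04 and mean of -0.07 differed in sign (camera adjusted p = 0.823): STARD4, a sterol carrier, fell by 1.31. Of 11 LXR targets, 1 rose and 2 fell, or 3 and 2 when adjusted over the list alone (camera adjusted p = 0.682). Of 25 fatty acid synthesis genes, 2 rose and 3 fell, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.446): ACSL3, which activates fatty acids, fell by 0.84. Of 26 genes of the tricarboxylic acid cycle, 4 rose and 4 fell, or 6 and 4 when adjusted over the list alone, and the median of 0.10 and mean of -0.12 differed in sign (camera adjusted p = 0.682): IDH3A, a dehydrogenase, fell by 0.88. Of 34 S phase genes, 1 (CCNE1) rose and 5 fell, or 1 and 2 when adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.568): CDC6, a licensing factor, fell by 1.39. Without normal glucose 3 the S phase median was 0.40 (camera adjusted p = 0.0486; 10 rose and 5 fell). CCNE1, a cyclin, rose by 0.72 and had an edgeR adjusted p of 0.0592, 0.069 and 0.0733 without high glucose 1, 2 and 3. Of the 7 measured endothelial markers, 2 fell, or 3 when adjusted over the list alone (camera adjusted p = 0.0549, and 0.033 and 0.0489 without high glucose 2 and 3).

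The tests of single libraries, of glucose use, of osmolality and of the run on chromosome 6 were chosen only after the results were seen. The tests of transcript length, of loci with a second gene and of other splits of the libraries were written before their values were known, though after the patterns were. With 6 libraries only 10 splits exist, too few for a share under 0.05. Each other split also mixes normal and high glucose libraries. The difference between the real groups then adds to the spread on each side, so few called loci there were likely from the start. The real split was the only 1 of the 10 with as many called loci (4906, highest other 1), loci called higher (2439, highest other 1), loci called lower (2467, highest other 1, taking the larger direction of each other split since its direction is arbitrary) and long non-coding loci (463, highest other 0). For gene lists called by camera, 3 of 10 splits, the real one included, reached the real 13 (highest other 13), so the number of called lists cannot be told apart from that of a grouping that puts normal glucose 1 and 2 together with 1 high glucose library. Such a grouping still sets normal glucose 1 and 2 against the other high glucose libraries. Part of the real difference stays in it, so its number of called lists is no measure of chance. Where normal glucose 3 lay differed between lists. It lay with the other normal libraries on the NFAT5 list (0.81, against 0.36, 0.63 and a high glucose range of -0.64 to -0.58). The same was seen on the ATF4 list (0.41, against 1.13, 1.30 and -0.96 to -0.94) and the complement list (-0.18, against -0.25, -0.40 and 0.26 to 0.31). It lay between the groups on the unfolded protein response list (-0.10, against 1.27, 1.39 and -0.86 to -0.84). So it did on the glycolysis (-0.03, against -0.36, -0.36 and 0.25) and NRF2 lists (0.12, against 0.60, 0.75 and -0.55 to -0.46). It was nearer to high glucose on the keratinocyte list (0.32, against -2.16, -0.46 and 0.64 to 0.90). On the G2 and M phase (1.2) and histone lists (1.06) it lay above all other libraries.

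The first pattern is the fall of the 49 unfolded protein response and ATF4 genes together, with a median log2 change of -1.65. Dependence on 1 normal glucose library did not account for it, since the median was -1.4, -1.45 and -1.95 without normal glucose 1, 2 and 3. The trend of the log2 change with relative transcript length was small: -0.18 to 0.06 over all loci and -0.02 to 0.06 at these genes. The median was -1.67 after the trend was removed. These values argue against a trend with transcript length as the source of the fall of these genes. A hypothesis left open is that glucose was used up in the normal glucose medium: normal glucose 3, with the lowest stress score (0.17, against 1.16 and 1.27), had a mean of TXNIP and ARRDC4 0.60 log2 units below the others (value -0.6), opposite to that idea, but 3 libraries are too few to decide.

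The second pattern is the lower median of the NFAT5 targets, of which 5 of 12 fell, 2 rose and 5 were not called, and the list was not called with an estimated correlation (camera adjusted p = 0.705). Hypertonic medium raises these genes, so higher osmolality of the high glucose medium would have raised their median. It was -0.87 (-0.97 to -0.68 over omitted libraries), opposite to that idea. That median also defined the pattern, so its direction was known beforehand and this is no separate test. Nor does it show that osmolality was equal. Loci that hold a second gene did not account for the lower median, since that of the 9 members in loci with 1 name was -0.88. The labels do not say whether an osmolyte was added to the normal glucose medium.

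The third pattern is the run of 27 loci on chromosome 6. It took the place of another pattern, the 83 loci counted in 1 group only, after the values of both had been seen; for those loci the highest number at another split was 8, and their 814 neighbours had a median log2 change of 0.15 in the direction of the locus. Copy number of a wider segment did not account for the run, since the 16 protein-coding loci within 1.5 Mb had a median of -0.21, although a change limited to the run was not tested. Genomic DNA did not either, since the other 3419 assembled loci had a median of -0.19. That the loci are parts of 1 long transcription unit is a hypothesis that fits 1 test: the SD of the log2 ratio of normal glucose 3 to libraries 1 and 2 was 34.1% of that over 2355 loci of like count. Any other change limited to the run could also move its loci together, so this value does not tell the hypothesis apart from such a change.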
